A study of Mus musculus with 16 samples.

How the data were processed

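RNA was measured in 4 libraries of cultured mouse cortical neurons, 1 per group, made with a total RNA kit and sequenced in paired ends, per the labels' protocols. The submitters' processing notes name TopHat, Bowtie, Cufflinks 2.0.0, Cuffdiff, BWA, Picard and HOMER and the mouse build mm9, with no role or order. The FPKM values were made by the authors and are used as deposited, with a gene symbol, a locus and an FPKM for each of 22440 genes per library. The authors also deposited 2 comparison tables, which give a gene, its locus and a control and a treated FPKM. They hold 692 genes for etoposide and 63 for NMDA, all with values equal, within a relative tolerance of 0.0001, to the library tables of the etoposide control pair and of the NMDA control pair. The rule by which genes were listed is not given in the sources used here, and these tables carry no p-value, so a stricter adjusted p was not run.

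Grouping followed the sample titles. Untreated, said of a control below, means that its title names no treatment. Each treated library was compared with the control whose FPKM stand in the authors' deposited table. The 12 chromatin samples were not analysed here. Fold was log2((treated + 1)/(control + 1)), with a pseudocount of 1 FPKM, for genes with FPKM of at least 1 in either library, and it understates the change of low genes. The size rule was at least 2-fold. Folds called as in the authors' deposited table are plain FPKM ratios. With 1 library per group no test was run. For 25 gene lists fixed before the data were examined, the median log2 fold was set against 10000 random lists of the same size matched on mean level in 20 bins, and percentiles below 2.5 or above 97.5 are called outside the central range, as a description of these libraries. Lists with fewer than 3 measured members got no median, and the list of mitochondrially encoded genes had 0 members in the tables. Relative medians are list medians minus the median of all genes compared. By this measure 7 lists of 22 lay below and 7 above the central range with etoposide, 8 and 5 of 24 with NMDA and 5 and 10 of 24 between the controls. Random draws of unrelated genes would give about 0.6 on each side of 24 lists. Members of a list can vary together between libraries, and some lists share members, so the 0.6 does not measure the spread between libraries. The untreated controls alone put 5 and 10 lists outside.

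Genomic span came from the loci in the tables, with 1 added to each start because the starts count from 0. Transcript lengths, gene types and overlapping exons came from the GENCODE annotation of the same build, matched for 21342 genes. The 3584 genes that share a locus with another gene were left out of the correlations with span, the span bins and the random lists matched on span. They were kept in the median spans and the shares of genes over 100 kb. The bootstrap spread of rho with span, from 200 resamples of genes, was 0.0087 for etoposide, 0.0102 for NMDA and 0.0097 between the controls. For other rank correlations no spread is given here.

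Depth was read from the low values. The FPKM of 1 fragment on 1 kb was near 0.0707 in the etoposide control, 0.0842 with etoposide, 0.0523 in the NMDA control and 0.0542 with NMDA, and 3 fragments on 1 kb correspond to 0.212, 0.253, 0.157 and 0.163 FPKM. The steps were taken from single-exon genes, and the fragment numbers and intervals made from them are approximate. The share of the normalization total that the listed exons account for was about 23.9%, 16.8%, 77.9% and 81.3% in the same order. This share moves every FPKM of a library alike. Values were compared within a pair for this reason, but the share also differed within the etoposide pair, so the FPKM ratios of etoposide and the 12 higher and 680 lower genes of the authors' deposited table carry that difference, and values relative to the median of all genes and median scaling are given beside them. Levels set across pairs are given with that limit. Mir5109, a microRNA locus, held 76.5%, 68.7%, 51.9% and 52.3% of the FPKM sum.

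Named genes were chosen by a rule written before the data were examined. They are the early-response transcription factors at FPKM of at least 1 in any library, the 10 largest folds each way per comparison, the 10 largest ratios each way in each of the authors' deposited tables, up to 4 members of each other list by size of fold, and Top2a and Top2b. Other genes named in the text were chosen after their values were seen. Some listed symbols were not analysed here, and some genes that these rules take are not reported here, though they stay in the list medians and counts. Where kits or counting do not tell strands apart, reads of genes with overlapping exons are uncertain, as are those of ribosomal protein and histone genes with near-identical copies.

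The steps were tested on simulated data made from each control library with noise on every gene. The 200 changed genes were drawn from those at FPKM of at least 5. For etoposide, over 10592 genes, the size rule took 27% of genes with a true 2-fold change, 99% at 3-fold and 100% at 4-fold, and 0 unchanged genes. For NMDA, over 12954 genes, it took 38% at 2-fold and 100% at 3-fold, and 0 unchanged genes. The simulated noise was smaller than the robust SD of the real folds with etoposide (0.442) and between the controls (0.530). It was larger than that with NMDA (0.133). The counts of 0 are therefore no error rate for these data. Between the untreated controls, 1042 genes were at least 2-fold higher and 385 lower relative to the median. Of unshifted lists, 1 of 22 and 1 of 24 fell outside the central range, and every list shifted by 0.5 was found.

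Alternatives were a pseudocount of 0.1, no level filter, FPKM of at least 5, a 4-fold rule, median scaling, the other control and the mean of both controls. Those chosen after seeing the data were the other control with median scaling, protein-coding genes only and random lists matched on level in 10 bins and span in 5 bins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.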

Results

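The series examined DNA breaks and early-response gene expression in primary cortical neurons from Swiss-Webster mouse embryos at embryonic day 16. Of its 16 samples, 4 are RNA-seq libraries and are described here. The other 12 are chromatin immunoprecipitation or input samples for γH2AX, a histone mark of DNA breaks, and for topoisomerase IIβ, and were not analysed here. The RNA-seq libraries came from a culture titled as control (the etoposide control) and a culture given 5 µM etoposide. The others came from a numbered further control culture (the NMDA control) and a culture given NMDA. The titles of the controls name no treatment. Etoposide traps type II topoisomerases on broken DNA, and NMDA activates a class of glutamate receptor. The labels give NMDA at 50 µM for 10 min with 10 min of recovery for most experiments, and give no length for etoposide. Each group had 1 library, so no difference below has a replicate check and no p-value is given.

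Each deposited table listed 22440 genes in FPKM (fragments per kilobase, scaled to the library's fragment total). The smallest steps between low values put the fragment totals used for normalization near 14.1 M in the etoposide control, 11.9 M with etoposide, 19.1 M in the NMDA control and 18.4 M with NMDA. FPKM of at least 1 was listed for 10459, 9836, 12886 and 12775 genes in the same order. Intervals below are exact 95% intervals of the ratio from those approximate fragment numbers and cover counting error only.

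Early-response transcription factors, which neurons switch on within minutes of activity, were among the genes higher with etoposide, the comparison that asks what trapped topoisomerase does to transcripts. The authors' deposited table listed 12 genes as higher, and Fosb, Fos, Nr4a2 and Npas4 were among them. Fosb (chromosome 7, 19888045 to 19895394, mm9) went from 0.0985 to 2.03 FPKM, 20.6-fold higher in the authors' deposited table (interval 8.85 to 67.6, from about 5 and 90 fragments). Fos (chromosome 12, 86814851 to 86818219) was 5.49-fold higher (3.92 to 7.93), at 2.68 and 14.7 FPKM. Nr4a2 (chromosome 2, 56959637 to 56976414) was 3.91-fold higher (2.61 to 6.00) and Npas4 (chromosome 19, 4984355 to 4989971), a factor specific to neurons, 2.65-fold higher (1.99 to 3.54). Relative to all genes, the log2 folds against the own control and against the other control were 2.42 and 0.89 for Fos and 1.78 and 1.58 for Fosb. They were 1.61 and 1.93 for Nr4a2 and 1.33 and 0.92 for Npas4. The size for Fos thus depended on the control. The pseudocount of 1 compresses folds of low genes, and the pairs lie on different FPKM scales. The near values for Fosb therefore do not show that its size held. As deposited, Fosb was no lower in the NMDA control than with etoposide. Ier2 at 1.82 and 5.46 FPKM, Atf3 at 1.15 and 2.80, Nr4a1 at 1.61 and 3.71 and Junb at 6.46 and 12.2 were also higher in the treated library but not listed by the authors. The family did not move as a block. Egr3 was at 3.78 FPKM in the control and 1.14 with etoposide, Srf at 4.40 and 1.84, Egr1 at 4.58 and 3.45, and Klf10 (4.26 and 1.63) was in the authors' deposited table as lower. Over the 20 members of this list that were measured, the median log2 fold lay 0.76 above that of all genes and above all 10000 random lists of the same size and level.

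**Figure D1:**
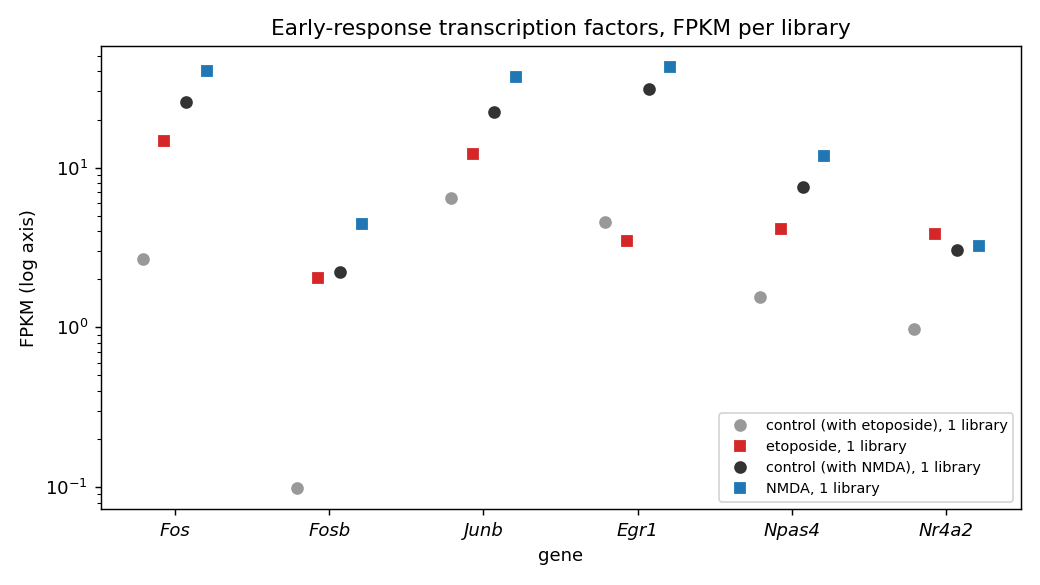
FPKM (log axis) of 6 early-response transcription factors, chosen for display after their values were seen, with 1 point for each of the 4 libraries and no error bars because each group had 1 library. Fos lay at 2.68 FPKM in the etoposide control, 14.7 with etoposide, 25.9 in the NMDA control and 40.2 with NMDA, and the pairs lie on different FPKM scales.

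The remaining genes that the authors' deposited table listed as higher with etoposide included transcripts of interneuron peptides. Cort (cortistatin) was 13.8-fold higher (interval 7.58 to 25.7), at 1.31 and 18.1 FPKM, and Sst (somatostatin) 2.54-fold higher (2.21 to 2.93), at 34.6 and 87.9 FPKM. Trim72 was 10.9-fold (interval 3.03 to 51.3, from about 3 and 25 fragments), Plekhg4 6.29-fold, 1700094D03Rik 4.21-fold and Rgs2, a brake on G-protein signalling, 2.18-fold higher. Rpl35 was 3.64-fold higher, but ribosomal protein genes have processed pseudogenes and their reads are uncertain. Exons of Plekhg4 and Rpl35 overlap another gene on the opposite strand, and those of 1700094D03Rik another gene on the same strand.

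The authors' deposited table listed 680 genes as lower with etoposide, with a median of 2.84-fold. Epha4 (chromosome 1, 77363760 to 77511663), a receptor that guides axons, went from 20.5 to 2.04 FPKM, 10.0-fold lower in the authors' deposited table (interval 8.48 to 11.9). Acta2, smooth muscle actin, was listed at 4.61 and 0.0944 FPKM, and the treated value stood for about 2 fragments, so its ratio of 48.9 has an interval of 13.2 to 407. Myl9, Cnn2, Rxfp3, C3 and Sox8 also had 4 or fewer fragments in the treated library, and Kcnj10, a glial potassium channel, went from 1.93 to 0.255 FPKM. Smoc2 was 11.6-fold lower in the same table. Of the enzymes that etoposide acts on, Top2b went from 24.2 to 12.5 FPKM (ratio 1.93, interval 1.65 to 2.27) and Top2a from 0.797 to 0.235, and neither was in the authors' deposited table.

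Lists of synaptic and sterol synthesis genes were lower with etoposide. All 34 measured long neuronal adhesion and synapse genes were lower, 12 of them in the authors' deposited table, and the list's median log2 fold lay 0.62 below that of all genes (relative value -0.62). Cdh13 went from 45.6 to 13.6 FPKM, Nlgn1 (neuroligin) from 13.9 to 4.11, and the NMDA receptor subunits Grin2b from 25.7 to 7.71 and Grin2a from 5.47 to 1.20. Glutamate receptor and postsynaptic genes had a relative median of -0.61, with 6 of 23 listed by the authors as lower, and presynaptic genes -0.44, with 2 of 20. All 15 measured sterol synthesis genes were lower, 8 of them in the authors' deposited table, at a relative median of -0.96. Among them Lss went from 26.5 to 8.11 FPKM. The sterol, long gene and glutamate receptor medians lay below all 10000 random lists, and the presynaptic median at percentile 0.1. With random lists matched on gene span as well, a match chosen after seeing the data, the long gene list lay at percentile 3.23 and the presynaptic list at 2.73, inside the central range, while the glutamate receptor list lay below that range at percentile 0.44 and the sterol list below all random lists. Against the other control after median scaling, also chosen after seeing the data, the relative medians were -0.31 for sterol genes (percentile 5.72) and -0.14 for presynaptic genes (percentile 26.0), both inside the central range, and -0.39 for glutamate receptor genes and -0.30 for long genes (percentiles 0.36 and 0.45), which lay at percentiles 4.52 and 48.0 when matched on span.

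Markers of every glial and progenitor list that could be measured were lower as well. The relative median was -0.54 for astrocyte markers (percentile 0.08, Slc1a2 17.7 to 6.80 FPKM), -0.67 for 3 oligodendrocyte lineage markers (percentile 0.73, Olig1 16.6 to 3.36) and -0.41 for 7 progenitor markers (percentile 0.84, Vim 72.5 to 24.4). With no level filter the oligodendrocyte median took the opposite sign. Of the progenitor markers, Ube2c was at 1.20 and 0.370 FPKM and Ccna2 at 1.08 and 1.04, so a fall of dividing cells is not shown. Pan-neuronal markers had -0.30 (percentile 2.83, Tubb3 209 to 101), excitatory neuron markers -0.23 (percentile 7.74, Slc17a7 25.4 to 10.3) and inhibitory neuron markers -0.14 (percentile 19.6, Calb2 9.49 to 3.35). The size of the glial and progenitor medians depended on the control, since against the other control after median scaling they were -1.63 for astrocyte, -2.16 for 12 oligodendrocyte lineage and -1.50 for progenitor markers. Microglial and vascular lists had fewer than 3 measured members and got no median.

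Several lists were higher than all genes with etoposide. Cytosolic ribosomal protein genes had a relative median of 0.71, replication-dependent histone genes 0.51 (Hist1h4a 18.0 to 42.6 FPKM) and small structured RNAs 0.80 (49 of 70 above 0), each above all 10000 random lists. Early-response effectors lay at 0.40 (percentile 100, Dusp1 3.36 to 6.86) and targets of p53, the factor that answers DNA damage, at 0.37 (percentile 99.97), although none of the 25 p53 targets was in the authors' deposited table (Pmaip1 3.41 to 6.26). Endoplasmic reticulum and amino acid stress genes lay at 0.27 (percentile 97.6, and 90.5 when matched on span, Ddit3 9.10 to 18.7). NF-kB targets at 0.38 (percentile 97.0, and 61.0 when matched on span, Cxcl1 1.96 to 4.93), late-response genes at 0.26 (percentile 96.7), topoisomerase and repair genes at 0.12 (percentile 80.8), glycolysis genes at 0.11 (percentile 69.0) and heat-shock genes at -0.0029 (percentile 49.3) lay inside the central range. Against the other control, the ribosomal, endoplasmic reticulum stress, glycolysis and inhibitory neuron medians and, among named genes at least 2-fold changed, Rpl35, Lss and Bcl11b took the opposite sign relative to all genes, and the heat-shock median was -0.81. With median scaling added, an alternative chosen after seeing the data, the medians were -0.77 for glycolysis genes (percentile 0.15), -0.57 for heat-shock genes (percentile 0.90), 0.14 for inhibitory neuron markers (percentile 78.9) and 0.02 for pan-neuronal markers (percentile 68.3). They were 0.45 for late-response genes (percentile 99.8, outside the central range), 0.73 for p53 targets (percentile 100, also when matched on span) and 0.39 for effectors (percentile 99.9), which lay at percentile 80.3 when matched on span.

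Longer genes were lower with etoposide. Genes listed by the authors as lower had a median span of 134.7 kb against 25.8 kb for all genes compared, and 411 of them (60.4%) spanned over 100 kb against 16.1% of all. Across 8880 genes, which are not independent replicates, Spearman's rho of log2 fold with span was -0.47, and the median log2 fold went from -0.09 in the shortest of 5 equal bins of genes to -0.70 in the longest. The same rho between the NMDA control and the etoposide control, both untreated, was -0.22, and against the NMDA control the etoposide library gave -0.07. Given transcript length and level, the partial rho was -0.30 for etoposide and -0.01 between the controls. After median scaling, the partial rho between the controls was -0.0603 at FPKM of at least 5 and -0.139 at FPKM of at least 20, the same direction as with etoposide. Fold with etoposide also fell with transcript length (rho -0.43, and -0.23 given span and level). Between the controls these were -0.36 and -0.28.

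**Figure D2:**
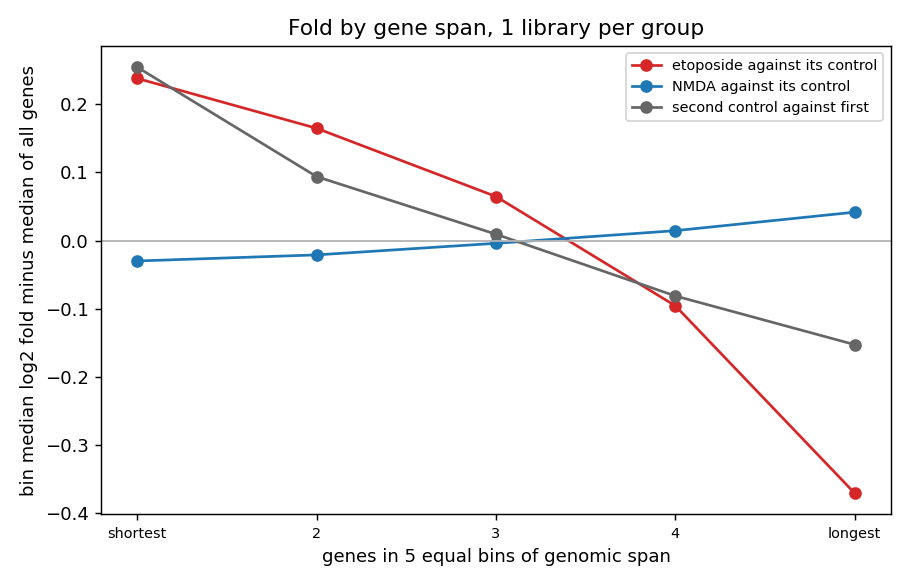
Median log2 fold of genes in 5 equal bins of genomic span, minus the median of all genes in the bins (y axis), for etoposide, NMDA and the pair of untreated libraries, with 1 library per group and lines joining the bins. The etoposide line goes from 0.24 to -0.37, the line of the controls from 0.25 to -0.15 and the NMDA line from -0.03 to 0.04.

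By the size rule, 51 of 10681 genes were at least 2-fold higher and 786 at least 2-fold lower with etoposide on the log2(FPKM + 1) scale. The median log2 fold of all genes was -0.32, and relative to it the split was 157 higher and 222 lower. With median scaling it was 304 higher and 289 lower, so the excess of lower genes depended on the scale. The 12 higher and 680 lower genes of the authors' deposited table are on the FPKM scale as deposited.

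NMDA, the comparison that asks what receptor activation does, gave smaller differences. The authors' deposited table listed 25 genes as higher and 38 as lower. Over the 23 higher ones above 0 in both libraries the median was 1.41-fold and the maximum 2.01-fold, and over the 34 such lower ones the median was 1.69-fold. Some early-response factors were on the higher side. Fosb was 2.01-fold higher in the authors' deposited table (interval 1.66 to 2.45, 2.21 to 4.46 FPKM), Junb 1.65-fold (1.51 to 1.81), Npas4 1.56-fold (1.39 to 1.76), Fos 1.55-fold (1.39 to 1.73) and Egr1 1.38-fold (1.30 to 1.47, 30.8 to 42.6 FPKM). These 5 were the members of the 23 measured factors that the authors listed, and the list's relative median was -0.04 (percentile 15.8), with 13 of the 23 below 0. Nr4a1 was at 11.5 and 13.6 FPKM, Jund at 45.1 and 44.4, Egr3 at 19.5 and 15.5 and Atf3 at 6.42 and 5.09, and none of the 4 was listed. The effector list lay at -0.10 (percentile 0.17), with Arc, a synaptic plasticity gene, at 7.27 and 9.66 FPKM and Gadd45b at 6.59 and 4.95. Against the etoposide control, the factor and effector medians were above that of all genes, at 0.23 and 0.08, but inside the central range (percentiles 97.3 and 81.9). With median scaling added they were 0.32 (percentile 99.2, and 93.6 when matched on span) and 0.01 (percentile 64.6).

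Long neuronal adhesion and synapse genes were slightly higher with NMDA against its own control, although Grin2b was the single member of the 39 measured that the authors listed. The authors' deposited table listed as higher Atg10 (1.93-fold), Epha6 (1.58-fold), Purg (1.52-fold), Grin2b (1.49-fold, 45.5 to 67.8 FPKM), Fat4 (1.45-fold), Pclo (1.44-fold) and Bsn (1.40-fold), the last 2 being scaffolds of the presynaptic active zone. The relative median was 0.14 for long neuronal adhesion and synapse genes (35 of 39 above 0, percentile 100, also when matched on span), 0.09 for presynaptic genes (all 20 above 0, percentile 99.4), 0.08 for glutamate receptor genes (percentile 99.2) and 0.09 for pan-neuronal markers (percentile 99.2). Matched on span as well, the last 3 lay inside the central range, at percentiles 92.8, 81.7 and 79.9. Spearman's rho of fold with span across 10721 genes was 0.18 against the NMDA control and -0.18 against the etoposide control, so this direction turned with the control, as did the long gene median and, with median scaling added, the presynaptic, glutamate receptor and pan-neuronal medians.

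On the lower side with NMDA, Meg3, an imprinted noncoding RNA, went from 267 to 111 FPKM, 2.41-fold lower in the authors' deposited table. Its exons overlap other noncoding genes. Abhd14b was 3.04-fold (interval 2.02 to 4.56), Cyp2e1 2.98-fold, Ybx2 2.70-fold, Rgs11 2.37-fold, Chrd 2.10-fold, Rtbdn 2.07-fold, Slc16a3, a lactate transporter, 1.90-fold, Vwa5b2 1.88-fold and Ssh3 1.87-fold lower in that table. Glycolysis and hypoxia genes had a relative median of -0.20, below all 10000 random lists, with Vegfa at 30.2 and 24.1 FPKM and Ldha at 347 and 301. NF-kB targets lay at -0.24 (percentile 1.02, Relb 4.59 to 2.49), microglial markers at -0.38 (3 members, percentile 1.54), astrocyte markers at -0.07 (percentile 1.50, Gfap 113 to 93.9), oligodendrocyte lineage markers at -0.10 (percentile 1.51), ribosomal protein genes at -0.03 (percentile 1.28) and small structured RNAs at -0.19 (percentile 0). Matched on span as well, the NF-kB (percentile 6.17), microglial (5.66), oligodendrocyte (3.39), ribosomal (12.3) and small RNA (18.4, from 11 members with a locus of their own) lists lay inside the central range, and the glycolysis (0.01) and astrocyte (0.81) lists below it. Against the etoposide control, the glycolysis, astrocyte, oligodendrocyte, ribosomal and small RNA medians were above that of all genes instead, and after median scaling so were, of the genes in this paragraph at least 2-fold changed, Ybx2 and Rgs11.

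The other lists moved little with NMDA against its own control. The relative median of histone genes was 0.06 (percentile 99.4, and 100 when matched on span), outside the central range. Against the etoposide control the histone list lay inside it, at percentile 87.5. Relative medians inside the range were 0.06 for inhibitory neuron markers (percentile 95.9), 0.05 for sterol synthesis genes (percentile 84.7), 0.01 for late-response genes (percentile 72.3), 0.01 for excitatory neuron markers (percentile 51.3) and 0.01 for endoplasmic reticulum stress genes (percentile 37.3). They were 0.0038 for topoisomerase and repair genes (percentile 66.4), -0.03 for heat-shock genes (percentile 20.0), -0.03 for vascular markers (percentile 42.4), -0.05 for p53 targets (percentile 4.71) and -0.08 for progenitor markers (percentile 6.13). Against the etoposide control after median scaling, several of these medians were further from 0, at 0.99 for progenitor markers, 0.87 for vascular markers, 0.68 for heat-shock genes, 0.52 for endoplasmic reticulum stress genes, -0.26 for excitatory neuron markers, -0.28 for p53 targets, -0.31 for inhibitory neuron markers and -0.38 for sterol synthesis genes. Top2b was at 58.5 and 67.7 FPKM and Top2a at 11.8 and 11.5. By the size rule, 57 of 13028 genes were at least 2-fold higher and 95 lower, but among protein-coding genes, a restriction chosen after seeing the data, there were 6 and 9. The 10 features with the largest fold each way, in both treatments, were small RNAs listed at 0 in the treated or the control library, so no fold is given.

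**Figure D3:**
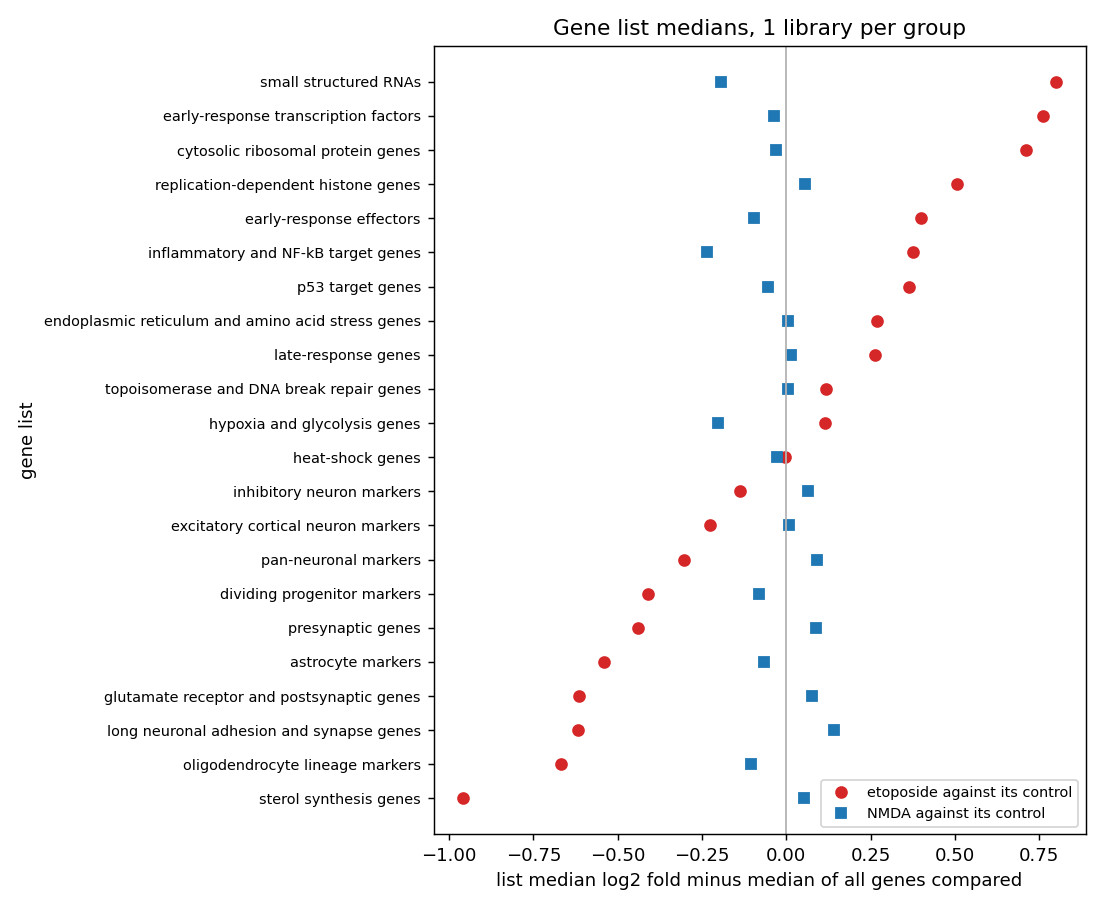
Median log2 fold of each fixed gene list with at least 3 members measured in both treatments, minus the median of all genes compared (x axis), for etoposide and NMDA, each against its own control with 1 library per group. Sterol synthesis genes lie at -0.96 and early-response transcription factors at 0.76 with etoposide, while the NMDA points lie between -0.24 and 0.14.

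Across the treatments, 3 genes were in the authors' deposited table as higher in both, namely Fos, Fosb and Npas4, where independent lists would share 0.0196. Another 7 were lower with etoposide and higher with NMDA, namely Cacna1e, Epha6, Fat4, Grin2b, Lrrc7, Odz1 and Pcdh19, named because they were shared, against 1.46 for independent lists. None was lower in both, against 1.58. These overlaps cover only the listed genes among the 10573 that passed the level filter in both comparisons. Those were 9 higher and 669 lower with etoposide, and 23 higher and 25 lower with NMDA. The numbers for independent lists take no account of gene span. Of the genes lower with etoposide 60.4% spanned over 100 kb, and of those higher with NMDA 52%, against 16.1% and 16.4% of all. Span alone would thus make the 1.46 too low. Across 10573 genes, which are not independent replicates, the log2 folds of the treatments had a Pearson r of -0.36 and a Spearman rho of -0.27, and across the 10219 protein-coding ones -0.23 and -0.27. The rho of fold with span was -0.47 with etoposide and 0.18 with NMDA, and these correlations were not separated from span.

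The untreated libraries differed from each other more than either treated library did from its own control. The NMDA control had 9754 of 12987 genes at least 2-fold higher than the etoposide control and 92 lower, around a median log2 fold of 1.32, and relative to that median the split was 1042 and 385. Spearman's rho of FPKM across genes was 0.868 between the controls, 0.939 between etoposide and its control and 0.963 between NMDA and its control. Relative to all genes, the NMDA control had higher medians for astrocyte markers (1.34), oligodendrocyte lineage markers (1.18), progenitor markers (0.84), heat-shock genes (1.03) and ribosomal protein genes (2.39), and lower medians for sterol synthesis genes (-0.18, percentile 0.09) and long neuronal adhesion and synapse genes (-0.27, below all 10000 random lists). The authors' deposited tables hold the values of these same pairs, so levels are compared here within a pair.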

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

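The other control with median scaling, the restriction to protein-coding genes and the random lists matched on gene span were chosen after seeing the data, and the other alternatives before. Values for lists and genes are log2 folds relative to all genes. Counts are genes at least 2-fold higher or lower unless stated, and the cause of a change was not tested where none is named. No paired analysis was possible because each group had 1 library. The stricter adjusted p for the authors' deposited tables was not run, as they carry none, and the overlap was not run on the mean of both controls, which the treatments would share. Differences within the counting intervals were not detectable. With 1 library per group, larger ones cannot be told apart from differences between libraries, which those intervals leave out. With a pseudocount of 0.1, etoposide gave 127 higher and 1551 lower genes, a rho with span of -0.476, an early-response factor median of 0.97 and a long gene median of -0.75. Genes lower in both treatments were 2, and the rho between treatments was -0.252. With no level filter, rho with span was -0.375 for etoposide, 0.146 for NMDA and 0.0165 between the controls, and -0.235 between treatments. The etoposide medians were then 0.36 for early-response factors, -0.72 for long genes, -1.16 for sterol genes and 0.0347 for oligodendrocyte markers. At FPKM of at least 5, these rho were -0.567, 0.226, -0.316 and -0.344, and 55 genes were lower between the controls. The 4-fold rule, by construction, took fewer genes, 25 higher and 18 lower with etoposide and 1950 and 47 between the controls. Protein-coding genes alone gave 17 higher with etoposide, 6 higher and 9 lower with NMDA, 44 lower between the controls and 0 shared genes higher and 0 lower. Median scaling gave 304 higher and 289 lower genes with etoposide and 1144 and 314 between the controls. The rho with span was then 0.193 for NMDA and -0.239 between the controls, rho between treatments -0.242, genes lower in both 2 and the early-response median with etoposide 0.64.

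Against the other control, etoposide gave 95 higher and 10972 lower genes and NMDA 9840 higher, since the pairs lie on different scales. The rho with span was -0.0655 for etoposide and -0.181 for NMDA, rho between treatments was -0.766, and 5 genes were higher in both. With the controls swapped, both folds hold the difference between the pairs with opposite signs. The rho of -0.766 therefore does not tell how the treatments relate. Etoposide medians were -0.29 for long genes, -0.67 for sterol genes, -0.40 for endoplasmic reticulum stress genes and -1.75 for ribosomal genes. NMDA medians were 0.23 for early-response factors, 0.0764 for effectors, -0.0762 for long genes, -0.15 for sterol genes, 0.61 for glycolysis genes, 1.32 for astrocyte markers, 1.28 for oligodendrocyte markers, 2.31 for ribosomal genes and 0.61 for small RNAs. Rpl35 was at -2.24, Lss at 0.10 and Bcl11b at 0.17 with etoposide, and Hist2h3b at -3.16 with NMDA.

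Against the mean of both controls, 7854 genes were lower with etoposide and 176 higher with NMDA, and rho with span was -0.141 and -0.0485. Etoposide medians were 0.61 for early-response factors, -0.34 for long genes, -0.69 for sterol genes, -0.27 for endoplasmic reticulum stress genes and -1.35 for ribosomal genes. NMDA medians were 0.0724 for long genes, -0.0397 for sterol genes, 0.0234 for glycolysis genes, 0.16 for astrocyte markers, 0.14 for oligodendrocyte markers and 0.34 for ribosomal genes. Rpl35 was at -1.74 and Hist2h3b at -1.46.

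Against the other control after median scaling, etoposide gave 590 higher and 1281 lower genes and NMDA 996 and 317, with rho of -0.141 and -0.194. Etoposide medians were 0.58 for early-response factors, -0.30 for long genes, -0.31 for sterol genes, -0.23 for endoplasmic reticulum stress genes and -1.45 for ribosomal genes. NMDA medians were 0.32 for early-response factors, 0.0145 for effectors, -0.19 for long genes, -0.10 for glutamate receptor genes, -0.12 for presynaptic genes, -0.38 for sterol genes and -0.16 for pan-neuronal markers. They were 0.69 for glycolysis genes, 1.09 for astrocyte markers, 1.53 for oligodendrocyte markers, 2.11 for ribosomal genes and 0.34 for small RNAs. Rpl35 was at -1.87, Lss at 0.35 and Bcl11b at 0.0512 with etoposide, and Ybx2 at 0.31, Rgs11 at 0.19, Hist1h2aa at 0.14 and Hist2h3b at -3.12 with NMDA. The genes given here are those at least 2-fold changed that took the opposite sign. The naming rule gave 233 gene values for genes that were above 0 in both libraries and not left out of the text. Of these, 66 changed sign against the other control, 73 with scaling added and 35 against the mean of both. Of those changes, 4, 7 and 2 were in genes at least 2-fold changed against their own control. By more than the robust SD of all genes, 182, 174 and 126 values moved, so most of these values depend on the control.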

Other observations

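The contractile and matrix list, the noncoding list and all tests in this part were chosen after the patterns were seen, and for all tests but the 2 on gene span for sterol and early-response genes the expected outcome was set down after the value tested was seen. Genes of smooth muscle contraction and extracellular matrix were lower with etoposide, with 12 of 18 measured members in the authors' deposited table as lower and a relative median log2 fold of -0.75. Tnc went from 4.49 to 0.651 FPKM, Tagln from 4.82 to 0.760, Thbs1 from 2.51 to 0.415 and Fn1 from 1.61 to 0.301. With NMDA the same list had a relative median of -0.20, and Flna, which crosslinks actin, was at 41.7 and 25.8 FPKM and in the authors' deposited table as lower. Noncoding RNAs of imprinted clusters and of the nucleus had a relative median of -0.40 with NMDA, where Miat went from 23.0 to 12.8 FPKM, Snhg11 from 5.57 to 3.04 and Ipw from 144 to 104, and of 0.69 with etoposide, where Meg3 was at 117 and 151 FPKM and Malat1 at 498 and 680 but 5 of 12 measured members were below 0, among them Ipw at 42.1 and 20.6 and Mirg at 3.67 and 1.31. These members were picked from the same libraries, so the medians are not independent evidence of direction. Between the untreated controls, the relative median was 0.21 for the contractile and matrix list and -0.37 for the noncoding list. Those sizes are near the ones with NMDA. Neither list was set against the other control.

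Longer genes were lower with etoposide, at a Spearman rho of -0.47 with span. A trend with transcript length, as from RNA quality, is argued against as the whole cause by the partial rho of -0.304 given transcript length and level. Fold also fell with transcript length given span and level, however (partial rho -0.228, and -0.285 between the controls). Loss of neurons with glia spared is argued against by astrocyte markers, which would then be relatively higher and had a relative median of -0.54. Loss of neurons together with glia cannot be judged this way, since oligodendrocyte lineage (-0.67) and progenitor markers (-0.41) were lower too. A control library out of line with other untreated cultures cannot be told apart from the treatment, as there is 1 library per group. The partial rho against the other control was -0.192 over all genes and -0.184 at FPKM of at least 5. It was -0.0688 at FPKM of at least 20, where the partial rho between the controls was -0.139. A slowing of transcription along long genes by trapped topoisomerase stays open as a hypothesis.

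Sterol synthesis genes were lower with etoposide. The trend with gene span is argued against, since the list median lay 1.03 below that of random lists matched on level and span (difference -1.03). A control library with high sterol gene levels is a candidate explanation, since against the other control after median scaling the difference from random lists was -0.283, at percentile 5.72, inside the central range, as was the median of -0.67 against the other control as deposited (percentile 3.09), while the -0.69 against the mean of both, which holds the control in question, lay below it (percentile 0.41). The NMDA control also had a lower sterol median than the etoposide control. An effect of etoposide stays open and was not separated from it.

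Early-response transcription factors were higher with etoposide. The trend with gene span is argued against by a list median 0.599 above that of random lists matched on level and span. Against the other control after median scaling, the list also lay higher, 0.559 above random lists, at percentile 100. The direction thus did not rest on the etoposide control alone. Random lists do not measure the spread between libraries, however. Between the untreated controls, 5 lists of 24 lay below and 10 above the central range, with relative medians such as 1.03 for heat-shock genes. This test therefore cannot decide whether a library difference is the cause. The NMDA control itself had a relative median of 0.23 for this list over the etoposide control, so a low etoposide control may account for part of the 0.76. An effect of etoposide is a hypothesis that 1 library per group does not settle.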
